A study of Xenopus tropicalis with 30 samples.

How the data were processed

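Whole bodies of adult *Xenopus tropicalis* (the western clawed frog) were profiled at both ends of their transcripts. WTSS-seq reads the 5′ ends, and so the transcription start sites, from RNA depleted of ribosomal RNA. WTTS-seq reads the 3′ ends, and so the poly(A) sites, from fragmented RNA enriched for poly(A) tails. Per the labels' protocols, total RNA was taken up in Trizol and the libraries were amplified by PCR after first-strand synthesis and size selection. CAGE, a method that captures the RNA cap, was run by a commercial service on a pool of 3 females. Per the series design, the same 6 males and 6 females entered both individual sets, and the pool of 3 females was also prepared as 2 WTSS-seq libraries.

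The authors deposited whole-number counts per site cluster and library in 2 tables, per the file headers and the values. A table of start sites holds 15 libraries and a table of poly(A) sites holds 12, so 27 of the 30 libraries in the labels were used and the remaining 3 (HATT-seq and 2 Iso-seq libraries) were not used here. The deposited tables also carry a total count per site, whose smallest value is 25 in both, so sites below that total are not analysed here. In the start table that total equals the sum of the 15 libraries. In the poly(A) table it adds up to 108811465 counts against 45443280 in the 12 listed libraries, so the list of poly(A) sites rests in part on counts not used here. The aligner, the clustering of reads into sites, the genome build and any other filter are not given in the sources used here. No column of another library was found (0 such columns).

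Groups were taken from the labels. Among the 6 male columns of start sites, 3 could not be tied to 1 animal, since their headers read Male3 once and Male4 in 2 columns, while the labels list males 2, 3 and 4. These 3 columns were used as male replicates without a number. Replicates are separate animals per the labels, so the error given is the spread between animals. The 2 columns headed Male4 were taken as 2 animals on that ground. Their headers do not settle it, and the male n of 6 in WTSS-seq rests on it.

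Each site has a sequence name, strand, position, start and end. Chromosome numbers were read from the sequence names, and all other sequences except the mitochondrial one were pooled as unplaced scaffolds. Positions count from 0 in the tables and were shifted to count from 1. The tables name no genes. The gene table at hand belongs to an assembly (UCB_Xtro_10.0) that the site tables do not name, so it was not used, no gene is named, and no exon, intron or UTR is assigned. In place of the planned genes, 2 kinds of units were built from the sites, and their definition was made after the tables had been seen. A run is a series of sites of 1 kind on 1 strand with at most 2000 bases between neighbours (500 and 5000 as alternatives). A start-to-end locus is a stretch of start sites followed on the same strand by poly(A) sites, with at most 20000 bases between neighbours (5000 and 50000 as alternatives). There were 28539 such loci with a median length of 7971 bases, and they held 91.8% of the poly(A) counts and 94.2% of the start counts. A run or locus may join neighbouring genes or split a long one.

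Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) between 6 males and 6 females of each assay, with TMM scaling, the filterByExpr filter by sex and Benjamini-Hochberg adjustment at 0.05. The TMM factors lay between 1.41 and 1.72 in female and between 0.543 and 0.787 in male WTTS-seq libraries. Levels are counts per 1000000 counts (CPM) on the TMM scale as mean ± SD, and the standard error of a log2 fold change is its size divided by the square root of F. Differences in site use within a run were tested with diffSpliceDGE and its F test per run. The dependence of the sex difference on the assay was tested as a sex by assay term over all 24 libraries. For the distal share, the 2 highest sites of each run with a mean of 20 or more counts over the animals were taken, 0.5 was added to each count, and the share of the more distal site was averaged over runs to 1 value per animal. The upstream share of start sites was formed likewise. Values per animal were compared with exact two-sided permutation tests over all 924 splits of 6 against 6, whose smallest possible p is 0.00216. Shares on 12 chromosomes or compartments formed a family for adjustment in each assay. Intervals of shares in single libraries are 95% Wilson intervals. Windows of 1000000 bases were compared with an exact hypergeometric test over the loci tested. Alternatives included DESeq2 1.42.0, limma 3.58.1, RLE size factors, library totals alone, no filter, a fold minimum, each library left out and a replicate block. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

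The sites named in the text follow a rule set before the data were examined, applied to sites, runs and loci without its demand for a gene symbol. They are the 10 largest changes in each direction with every animal of 1 sex above every animal of the other and a mean of 10 CPM or more in the higher sex. The 8 largest shifts in site use with at least 10% of the run in 1 sex, the 5 loci with the smallest p in each direction for the assay term and the 5 most extreme CAGE ratios in each direction were taken likewise. The 10 sites of highest mean level in each assay were added after the data had been seen. Not every site chosen is printed. The tests over genes, gene lists and authors' site classes that were planned before the data were examined could not be run, since the tables give none of these.

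The tests were tried on simulated counts with 50 altered sites for each of 4 sizes of change and the common dispersion of the real data. For WTTS-seq sites, 0% of changes of 2 and 36.0% of changes of 3 on the log2 scale were recovered among 20374 sites, with 0 false calls. For WTSS-seq sites, 64.0% and 80.0% were recovered among 17694 sites, with 1 false call. The test of site use was less strict than its nominal level: 10 of 46 simulated WTTS-seq calls (21.7%) and 26 of 140 WTSS-seq calls (18.6%) were false. The simulated runs paired sites at random. The share of false calls depends on how many runs are altered, so these shares are not rates for the real runs. Recovery likewise depends on how many sites are altered and on giving every site the common dispersion. The recovered shares are thus not those of the test on the real sites. Library totals ran from 2304469 to 6624765 counts in WTTS-seq and from 1866839 to 6643184 in the individual WTSS-seq libraries, so 3 counts correspond to between 0.452 and 1.61 CPM of the library total. Where 1 sex had 0 counts, a fold is given as a lower bound from 3 counts over the 6 libraries on the TMM scale of the levels (for CAGE on library totals), and with 1 to 3 counts it is a ratio with its 95% counting interval. PCR copies are not independent molecules, so intervals and floors cover counting error only.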

Results

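Transcription start sites and poly(A) sites were counted in whole adult frogs of both sexes. The start table held 69857 sites in 15 libraries: 6 females and 6 males by WTSS-seq, 2 repeat WTSS-seq libraries of a pool of 3 females, and 1 CAGE library of that pool. The poly(A) table held 98277 sites in 12 WTTS-seq libraries, from 6 females and 6 males. Totals ran from 2304469 to 6624765 counts per WTTS-seq library and did not differ between the sexes beyond the spread between animals (n = 6 each, exact permutation p = 0.734). Individual WTSS-seq libraries held 1866839 to 6643184 counts, likewise with no difference by sex beyond that spread (n = 6 each, exact permutation p = 0.727). The pool libraries held 1935959 and 9227896 counts, and the CAGE library 2641136. Sites lay close together: 26.6% of the 60601 poly(A) runs and 36.8% of the 38633 start runs held 2 or more sites. Among sites with a mean of 1 CPM or more these shares were 24.2% and 24.5%. A run held up to 40 poly(A) sites or up to 70 start sites.

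The first question was how the pool of transcripts differed between the sexes as a whole. In males the 3′-end counts were concentrated in fewer sites. The 100 highest poly(A) sites of a library held 51.4% ± 4.63 of its counts in males against 18.0% ± 0.997 in females (n = 6 each, exact permutation p = 0.00216, higher in 6 of 6 males than in any female). The upper 50% of the counts lay in 98.7 ± 38.1 sites in males and in 1057 ± 58.3 sites in females. Start sites were also more concentrated in males, at 59.3% ± 3.25 against 40.8% ± 18.9 (n = 6 each, exact permutation p = 0.0368), although female 3 of WTSS-seq stood at 78.3%. Without it the difference was 26.0 points (exact permutation p = 0.00216), but with another library left out p rose to as much as 0.0866. Mitochondrial sites took a larger share in males at both ends. Their share was 2.61% ± 0.460 against 0.611% ± 0.283 of poly(A) counts (adjusted exact permutation p = 0.00236, n = 6) and 2.46% ± 0.809 against 0.746% ± 0.409 of start counts (adjusted exact permutation p = 0.00866, n = 6). In both assays all 6 males lay above all females.

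**Figure D1:**
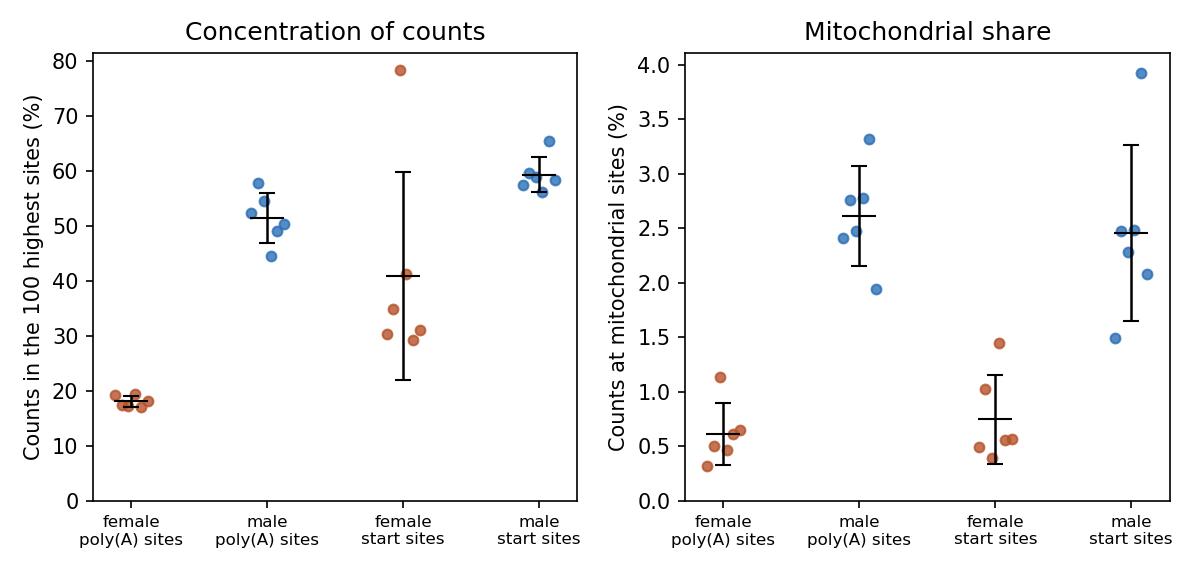
Share of each library's counts in its 100 highest sites (left, %) and at mitochondrial sites (right, %) in 6 females and 6 males of each assay. Points are animals, and bars are the mean ± SD. Males lay above all females in 3 of the 4 comparisons; in start sites female 3, at 78.3%, lay above the males.

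Single chromosomes carried these differences unevenly. In WTTS-seq, chromosome 7 rose from 7.55% ± 0.302 of counts in females to 11.8% in males (10.1% to 13.1%), chromosome 9 from 5.81% ± 0.211 to 8.27% ± 1.52, and the unplaced scaffolds from 11.4% ± 0.630 to 19.0% ± 5.76 (n = 6, adjusted exact permutation p = 0.00236 for each). Single sites carried most of the rises of chromosomes 7 and 9. The one at 105374171 on chromosome 7 held 960743 male and 73224 female counts, and that at 36978837 on chromosome 9 held 593311 and 58434. With each site counted once, the scaffold difference turned to -0.368 points (exact permutation p = 0.0823). Chromosome 10 stood at 4.86% ± 0.258 and 4.68% ± 0.356 (n = 6, exact permutation p = 0.342), and chromosomes 1 to 6 and 8 were lower in males. In WTSS-seq, chromosome 5 rose by 9.56 points over 6.46% ± 1.99 in females and chromosome 9 by 9.34 points to 14.8% ± 3.65 in males (n = 6, adjusted exact permutation p = 0.00866 for both). Chromosome 10 rose from 3.91% ± 1.32 to 5.88% ± 1.05, and chromosomes 1, 2, 3 and 6 were lower in males (n = 6, adjusted exact permutation p = 0.0227 for each). For these 4 the adjusted p was 0.00433 without female 3 but as much as 0.0714 without another library. At the start end chromosome 7 stood at 7.11% ± 1.89 in females and 8.03% ± 1.74 in males (n = 6, exact permutation p = 0.411; 0.208 points higher in males with each site counted once, exact permutation p = 0.00649), and chromosomes 4 and 8 did not pass the threshold (exact permutation p = 0.907 and 0.0563). Without female 3 the male difference was 0.210 points for chromosome 7 (exact permutation p = 0.820), -1.05 for chromosome 4 (p = 0.0606 by the same exact test) and -2.99 for chromosome 8, which then passed (adjusted exact permutation p = 0.00433). On chromosomes 5 and 9, 1 start site each rose by more than the whole chromosome did. The start site of the highest level on a chromosome lay at 61406537 on the plus strand of chromosome 5. It held 2.95e+06 male and 103949 female counts (147252 ± 11510 CPM in males against 4306 ± 2925 in females). A start site on chromosome 9 at 7178506 (plus strand) held 2.86e+06 and 56051 (134799 ± 34092 CPM against 2229 ± 1006). These CPM are on the TMM scale, whereas the shares are of library totals. Shares of 1 total are not independent, so a rise on 1 chromosome also lowers the shares of others. The scaffold share of start counts showed no difference past the threshold (22.8% ± 24.5 in females, 18.1% ± 8.18 in males, n = 6, exact permutation p = 0.838). Its difference of -4.73 points turned to 5.04 points without female 3 (exact permutation p = 0.333), in whose library 1 scaffold alone held 67.2% of the counts. With each site counted once it was 1.37 points (exact permutation p = 0.00216).

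The second question was which poly(A) sites differed between the sexes. Among 16429 sites tested, 4246 were higher in males and 4095 in females, with a median change of 3.47 on the log2 scale (3.47 also with the 478 sites at 0 counts in 1 sex set to their lower bound). Some were counted in 1 sex alone. A site on chromosome 8 at 14383936 (plus strand, cluster 14383796 to 14384281) had 1963 counts over the males and 0 over the females, at least 1674-fold higher, though males ranged from 22.8 to 685 CPM and their mean of 178 CPM was 76.2 without male 2 (edgeR adjusted p = 5.06e-05). Sites at 123958480 on chromosome 5 (plus, 76.4 ± 37.0 CPM, at least 946-fold) and at 35438806 on chromosome 3 (plus, 92.1 ± 55.0 CPM, at least 901-fold) were also found only in males (n = 6). On the minus strand of chromosome 4, a site at 5878134 held 795 male and 0 female counts, at least 678-fold higher, at a male mean of 47.7 CPM (30.6 without male 4). At 144522677 on chromosome 5 (minus strand) there were 2780 male counts against 1 female count, a ratio of 7113 with a 95% counting interval of 1276 to 281040. Males ranged from 46.7 to 491 CPM, with a mean of 163 CPM (97.8 without male 4).

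Among the poly(A) sites with the largest changes, the female ones had higher levels than the male ones. On chromosome 2 a site at 77286553 (minus strand, cluster 77286445 to 77286920) stood at 1340 ± 287 CPM in females and at 0 counts in the 6 males, at least 5685-fold higher (edgeR adjusted p = 3.73e-08). Sites on chromosome 8 at 503681 (minus, 1147 ± 209 CPM), chromosome 7 at 112753832 (plus, 1098 ± 345 CPM) and chromosome 10 at 31529720 (minus, 803 ± 98.0 CPM) also had 0 male counts and were at least 5181-fold, 4635-fold and 3583-fold higher in females. Chromosome 4 held 2 more such sites, at 38551331 (minus, 456 ± 75.6 CPM) and 35831357 (plus, 312 ± 115 CPM). A site at 119177743 on chromosome 3 (plus strand) was likewise at 0 in males but uneven in females, from 32.7 to 7483 CPM, with a mean of 1294 CPM that was 56.7 without female 4.

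The 10 poly(A) sites with the highest mean level were all higher in males. The first of them, at 105374171 on chromosome 7 (plus strand), stood at 71436 ± 12523 CPM in males and 2241 ± 1078 in females, a log2 change of 4.99 with a standard error of 0.34 (edgeR adjusted p = 7.54e-08, n = 6). Sites at 36978837 on chromosome 9 (minus strand, 43963 ± 22151 against 1937 ± 857 CPM), at 134367210 on chromosome 2 (minus, 23665 ± 5446 against 3042 ± 991) and at 49712987 to 49713963 on chromosome 8 (plus, 16725 ± 7953 against 633 ± 341) followed the same direction. Of 13 mitochondrial poly(A) sites tested, 12 were higher in males and 0 in females. The balance of directions depends on scaling: relative to library totals alone, all sites shift by -1.25 on the log2 scale, and 2627 sites were then higher in males and 7462 in females (26.0% against 50.9% of calls male under TMM).

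Start sites were compared in the same way. Of 15050 tested, 5055 were higher in males and 5546 in females, with a median change of 2.85 on the log2 scale (2.85 also with the 286 sites at 0 counts in 1 sex set to their lower bound). On the minus strand of chromosome 9, a start site at 5318495 held 8468 male counts against 1 female count, a ratio of 11158 (95% counting interval 2002 to 440752), with males from 5.17 to 998 CPM and a mean of 309 CPM (172 without male 5). At 5878907 on chromosome 4 (minus strand) 2567 male counts stood against 1, a ratio of 3382 (607 to 133646), but males ranged from 7.38 to 387 CPM and their mean of 91.0 CPM was 31.8 without male 5. This start lies upstream of the male-only poly(A) site at 5878134 on the same strand. A start site at 14376436 on chromosome 8 (plus strand, 606 counts in males and 0 in females, at least 266-fold, mean 28.1 CPM, or 17.1 without the male library headed Male3) likewise lies upstream of the male-only poly(A) site at 14383936. At 8016701 on chromosome 9 (plus strand) males had 25.7 CPM (9.74 to 55.2) and females 0 counts, at least 217-fold higher (edgeR adjusted p = 1.06e-06).

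Female start sites included 81244983 on chromosome 2 (minus strand, cluster 81244661 to 81245445), at 236 ± 41.3 CPM in females and 0 counts in males, at least 1520-fold higher (edgeR adjusted p = 2.02e-08, n = 6). On the plus strand of that chromosome, start sites at 144100545 (122 ± 71.0 CPM, at least 926-fold) and 144103174 (2410 ± 1874 CPM, 79572 against 9 counts) preceded the female-only poly(A) site at 144110896 (440 ± 88.3 CPM, at least 1872-fold). A site at 104601115 on chromosome 7 (plus strand) was even between females, at 92.8 ± 10.4 CPM, with 0 male counts (at least 630-fold). On the minus strand of chromosome 9, start sites at 77005397 (1073 ± 222 CPM) and 77003275 (97.1 ± 44.1 CPM) were female, with 4 and 0 male counts. Among the most abundant start sites, 39401987 on chromosome 2 (minus strand) was higher in females, at 27178 ± 10465 against 2242 ± 311 CPM. Of 26 mitochondrial start sites, 22 were higher in males and 0 in females. With library totals alone the shift was -0.66, with 4038 sites higher in males and 6899 in females (36.9% against 47.7% male).

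Chromosomes also differed in the direction of their start sites. Unplaced scaffolds had 664 sites higher in males and 463 in females (58.9% male, Fisher's exact adjusted p = 1.79e-14). On chromosome 9, 424 were higher in males and 315 in females (57.4% male, Fisher's exact adjusted p = 2.17e-07), and on chromosome 10 there were 276 and 202 (57.7%, Fisher's exact adjusted p = 1.92e-05). Of the chromosome 9 sites, 69 of the male-higher and 5 of the female-higher ones lay in 1 window, from 58000001 to 59000000. Chromosome 7 had 422 and 385 (52.3%, Fisher's exact adjusted p = 0.0114). On chromosome 1 the balance went the other way, with 508 and 787 (39.2%, Fisher's exact adjusted p = 4.36e-10), and chromosomes 2, 3 and 6 also had fewer male-higher sites (42.9%, 44.3% and 43.3%, Fisher's exact adjusted p = 0.000949, 0.0252 and 0.0252). For poly(A) sites only chromosome 1 (480 and 570, 45.7% male) and the mitochondrial sequence passed the threshold (Fisher's exact adjusted p = 0.00297 for both). Sites are not independent of their neighbours, and these p-values treat them as if they were.

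A stretch of chromosome 9 was rich in male-higher loci at both ends. It was singled out after its values had been seen, as the window of 1000000 bases with the smallest p. From 58000001 to 59000000, 62 of 65 loci tested by WTSS-seq and 20 of 24 tested by WTTS-seq were higher in males (adjusted exact hypergeometric p = 9.33e-25 and 4.44e-06). Its summed start level was 2618 ± 868 CPM in males against 219 ± 45.9 in females, and its poly(A) level 1330 ± 415 against 437 ± 108 (n = 6 each), with no test of these levels since the window was chosen for its male-higher loci. Of its 332 start sites, 316 were on the plus strand. Further windows past the threshold in both assays began at 45000001 and 73000001 on chromosome 7, 12000001 on chromosome 4, 57000001 on chromosome 8, 39000001 on chromosome 10 and 144000001 on chromosome 5. All of these 7 windows were male-higher.

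**Figure D2:**
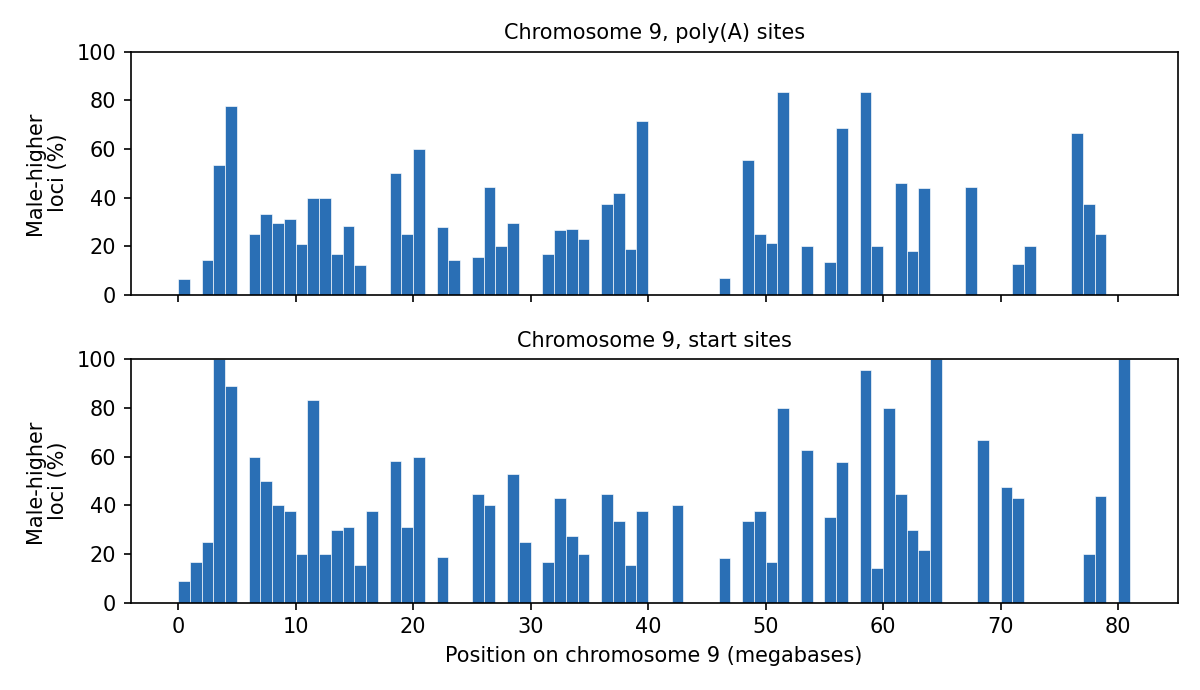
Share of the loci tested that were higher in males (%) in each window of 1000000 bases along chromosome 9 (megabases), for loci counted at their poly(A) sites (top) and at their start sites (bottom). Windows with under 5 loci are not drawn, and a window at 0% shows no bar. The window from 58000001 to 59000000 held 20 of 24 male-higher loci at the poly(A) end and 62 of 65 at the start end.

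Because both ends were read in the same set of animals, the sex difference of a locus could be compared between assays. Of 12576 loci tested by WTTS-seq, 3274 were higher in males and 3310 in females, and of 12197 tested by WTSS-seq 3975 and 4429 (edgeR). Library totals alone gave 1861 and 6446 for WTTS-seq (22.4% male, shift -1.37) and 2925 and 6009 for WTSS-seq (32.7% male, shift -0.79). Over the 5401 loci tested in both, the log2 sex differences of the assays correlated across loci with Pearson's r = 0.845 and Spearman's rho = 0.811, and 81.1% had the same sign. Loci are not independent replicates. Neighbouring loci, as a control, gave r = 0.142. Among 2478 loci called in both, 2396 went the same way and 82 opposite ways. Male-higher loci shared by both assays numbered 1266 where independent lists would give 515, and female-higher loci 1130 where they would give 502. The animals are shared, so part of this excess can come from the animals themselves.

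For 599 of the 5401 loci the sex difference itself depended on the assay (edgeR, sex by assay term). The male-to-female ratio was higher at the start end in 329 and lower in 270; with RLE size factors the balance turned, to 266 and 346. On the plus strand of chromosome 3, a locus from 123810970 to 123845671 had 2.24 ± 1.51 CPM in females and 120 ± 35.6 in males at its starts but 135 ± 165 and 9.56 ± 7.60 at its poly(A) sites (edgeR adjusted p = 1.40e-07, n = 6). The minus strand of chromosome 2 from 93866189 to 93879884 went the same way, with 0.412 ± 0.468 and 10.4 ± 2.44 CPM at its starts and 25.4 ± 18.2 and 0 at its poly(A) sites. On chromosome 10 (plus strand, 16696710 to 16729210) the order was the opposite: starts fell from 113 ± 41.5 in females to 9.59 ± 3.00 CPM in males while poly(A) sites rose from 2.85 ± 1.43 to 24.7 ± 14.7. A locus on chromosome 6 (minus strand, 77508485 to 77518958) had 309 ± 64.1 and 122 ± 34.4 CPM at its starts but 803 ± 170 and 5420 ± 1102 at its poly(A) sites (edgeR adjusted p = 1.02e-07). The number called depended on the settings. It was 167 with sex and replicate number together as a block (390 in those libraries without it) and 333 of the 2351 loci with a mean of 10 CPM or more. With gaps of 5000 and 50000 bases it was 338 of 3779 and 794 of 5957. A locus can hold more than 1 transcript.

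Which of several poly(A) sites was used differed between the sexes in 357 of 2491 runs tested. Males had the higher share of the distal site in 280 of the 357 runs and females in 77, with a median difference of 32.7 percentage points. Over all runs tested, called or not, these were 1586 and 905. In a run on chromosome 1 (plus strand), the distal site at 154085496 held 3.00% ± 3.58 of the counts in females and 83.0% ± 13.6 in males, and the proximal site at 154082438 held the remainder (n = 6, edgeR adjusted p = 5.52e-05, at least 20 counts in every library). On chromosome 4 (minus strand), the most distal of 3 sites, at 36155384, rose from 13.2% ± 12.3 to 92.7% ± 7.30, with as few as 8 counts in a library (n = 6, edgeR adjusted p = 0.000192). At 67051899 on chromosome 2 (plus strand) the share rose from 7.45% ± 17.4 to 93.3% ± 6.53, with as few as 5 counts (n = 6, edgeR adjusted p = 0.00210). On chromosome 10 (minus strand) the most proximal of 3 sites, at 10661329, held 82.4% ± 13.8 in females and 0% in males, with at least 9 counts in each library (n = 6, edgeR adjusted p = 2.01e-05). The Simes form of the test called 175 runs. About 21.7% of calls were false in simulated data, whose runs paired sites at random, so the rate for the real runs is not known.

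Start site use differed in 476 of 1965 runs. The more upstream start had the higher share in males in 207 runs and in females in 269, with a median difference of 22.9 percentage points. Over all runs tested these were 929 and 1036. Some runs switched almost completely. On chromosome 8 (minus strand), females used the start at 52870559 for 98.9% ± 1.08 of the counts, whereas males had all counts at 52867994, from as few as 7 counts in a library (n = 6, edgeR adjusted p = 4.24e-12). On the plus strand of that chromosome, the upstream start at 59093526 held 90.0% ± 6.75 in females and 0.152% ± 0.371 in males, the other counts lying at 59094157, with at least 27 counts in every library (n = 6, edgeR adjusted p = 5.68e-12). In a run of 3 starts on chromosome 1 (minus strand), the middle start at 35947316 rose from 3.95% ± 1.91 to 88.4% ± 5.25 (n = 6, edgeR adjusted p = 8.40e-15, at least 81 counts). On chromosome 2 (minus strand), the start at 77245896 held 91.3% ± 2.08 in females and 9.03% ± 2.97 in males, with at least 103 counts (n = 6, edgeR adjusted p = 1.53e-11). Without female 3 of WTSS-seq 736 runs were called. About 18.6% of calls were false in simulated data with runs paired at random, which is likewise not a rate for the real runs.

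Averaged over runs, the more distal of the 2 main poly(A) sites held a larger share of the counts in males. The 2 sites of a run may end different transcripts or neighbouring genes. The mean distal share over 8599 runs was 60.1% ± 0.882 in males and 57.0% ± 0.753 in females, 3.07 percentage points higher (n = 6 each, exact permutation p = 0.00216, all males above all females). The difference lay in widely spaced sites. Where the sites were 1000 bases or more apart, the share was 61.8% ± 1.19 in males and 54.7% ± 0.912 in females (3387 runs, difference 7.06, n = 6, exact permutation p = 0.00216). At 500 to 1000 bases the difference was 2.20 points (2110 runs, n = 6, exact permutation p = 0.00216). Below 500 bases it was -0.685 points (3102 runs, n = 6, exact permutation p = 0.167). With runs joined over gaps of at most 500 bases it was 0.434 points (n = 6, exact permutation p = 0.271).

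**Figure D3:**
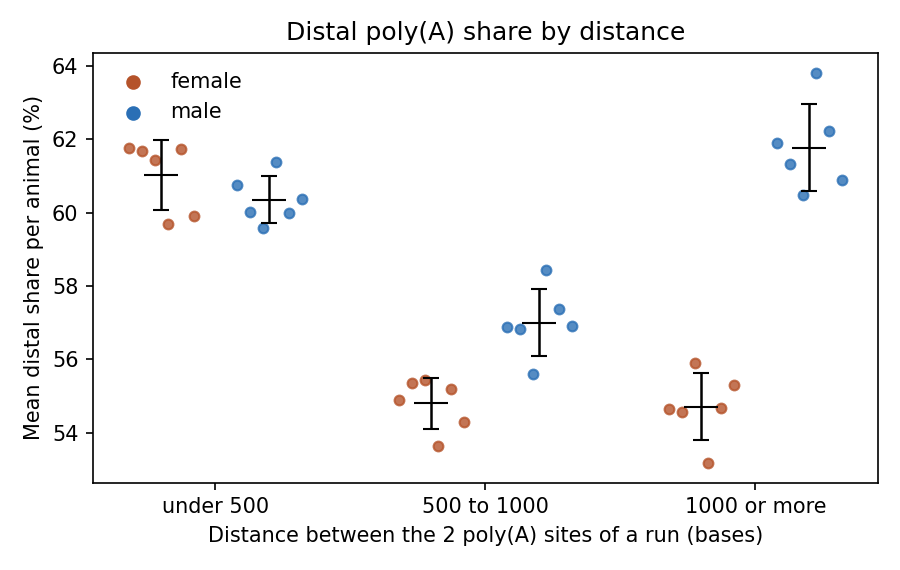
Mean share (%) of the more distal of the 2 main poly(A) sites per animal, for runs grouped by the distance between these sites in bases. Points are 6 females and 6 males, bars are the mean ± SD, and the vertical axis does not start at 0. At 1000 bases or more all males lie above all females, with means of 61.8% and 54.7%.

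The upstream share of start sites showed no such difference between the sexes at this number of animals. It was 56.1% ± 0.803 in males and 57.4% ± 1.73 in females over 5763 runs (n = 6 each, exact permutation p = 0.132). Female 3, at 54.1%, lay below the other females, and without it the difference of -1.96 points passed the threshold (exact permutation p = 0.00433).

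The last question was how well start sites are measured, from 1 pool of female RNA prepared as 2 WTSS-seq libraries and 1 CAGE library. The repeats shared 46317 sites, which held 99.2% and 96.2% of their counts, and their log2(CPM + 1) values correlated across 63673 sites with Pearson's r = 0.745 and Spearman's rho = 0.575. Pairs of different females gave Pearson's r between 0.731 and 0.767 in pairs with female 3, and between 0.856 and 0.913 in the others. The repeats thus correlated less than any pair of females without female 3. Their depths also differed, at 1935959 and 9227896 counts. A run on chromosome 4 (minus strand, 36688436 to 36691433) had 24166 counts in the second repeat (2619 CPM) and 1 in the first (0.517 CPM), with 0 in CAGE.

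CAGE and WTSS-seq shared their main sites in part, at different levels. Of 63673 sites with WTSS-seq counts in the pool and 33280 with CAGE counts, 31679 had both, and of pool sites with 25 or more WTSS-seq counts 61.1% had a CAGE count. Sites with WTSS-seq counts in the pool held 96.0% of CAGE counts, and sites with CAGE counts held 86.4% of pool WTSS-seq counts. Across 65274 sites Pearson's r was 0.421 and Spearman's rho 0.307, and of the 1000 highest sites of each method 224 were shared, against 615 between the repeats. On chromosome 3 (minus strand), positions 16290815 to 16290817 held 14325 CAGE counts (5424 CPM) and 0 in the WTSS-seq libraries of the pool, at least 20183-fold higher in CAGE. Positions 27650012 to 27650027 on chromosome 10 (plus strand, 1251 CPM, at least 4655-fold) and 83513466 to 83513489 on chromosome 1 (plus strand, 1114 CPM, at least 4147-fold) were also seen in the pool by CAGE alone. Runs seen in the pool by WTSS-seq alone included 15708106 to 15708532 on chromosome 9 (minus strand, 1252 CPM over both repeats, at least 1102-fold, but 69.7 and 1499 CPM in the first and second) and 37524431 to 37524455 on chromosome 2 (plus strand, 1018 CPM, at least 897-fold, with 488 and 1130 CPM). Within 2666 runs, the mean upstream share was 60.6% by CAGE and 45.0% by WTSS-seq, and it was higher by CAGE in 1833 and lower in 790. Mitochondrial sites held 1.28% of CAGE counts (95% Wilson interval 1.26 to 1.29) and 0.601% (0.590 to 0.612) and 0.689% (0.684 to 0.694) of the repeats. With 1 CAGE library there is no replicate check on these differences.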

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

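The correlation of 2 start sites of an unplaced scaffold, those highest in female 3 of WTSS-seq, was the only test of this part chosen after the result was seen. Over 24 groups and measures, 4 libraries' values stood apart by Dixon's criterion at 95%, under which chance gives about 1 in 20. They came from 2 libraries and are not independent. Of these, 3 concerned female 3 of WTSS-seq: its 100 highest start sites held 78.3% of its counts (29.2% to 41.2% in the other females), unplaced scaffolds held 71.7% (at most 23.3% in the others), and its mean upstream share was 54.1% (57.5% to 59.1%). The fourth was the first male library headed Male4, in which unplaced scaffolds held 34.4% of the start counts (at most 17.1% in the other males).

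Behind the scaffold shares stood 1 sequence. It held 67.2% of the start counts of female 3, 15.5% of female 4, 26.1% of the first library headed Male4 and between 1.56% and 8.71% of the other individual WTSS-seq libraries, but no more than 0.0596% of any WTTS-seq library. Outside it, female 3 still had 1968673 counts, close to the 2019096 of female 2. A wrong sex label is argued against, since with the scaffold left out the mean Spearman correlation of female 3 was 0.0766 with the males and 0.711 with the other females. That 0.711 lay below the range of the other females (0.806 to 0.855), so a poor or mixed library stays open. A common source may lie behind the scaffold, since its 2 start sites highest in female 3 rose and fell together over 14 WTSS-seq libraries (Pearson's r = 0.969, permutation p = 0.000210; 0.904 without the 2 farthest libraries; Spearman's rho = 0.609, permutation p = 0.0252). Choosing the sites by their level in female 3 raises r in part. The permutations also treat the 2 libraries of the pool as independent. No biological explanation was tested.

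The sex difference of 599 loci depended on the assay, by a test of the sex by assay term. In 2 of 50 random splits of the libraries, the real one included, as many loci were called, but splits that mix the sexes put the large sex difference into the spread. They give no measure of chance for this term, which stays open. The other such split gave 1508 calls. It kept the sex of all 12 WTTS-seq libraries and mixed that of 6 of the 12 WTSS-seq libraries, so it measured the sex difference of WTTS-seq itself. The next highest gave 1.

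For the sites that differed between the sexes, only the real split among 50, that is 1, gave as many calls. It gave 8341 poly(A) sites (highest other split 311) and 10601 start sites (2). For loci it gave 6584 in WTTS-seq (15) and 8404 in WTSS-seq (2). For site use it gave 357 runs of poly(A) sites (1) and 476 runs of start sites (55). For each of these 6 counts, 1 split in 50 argues against an arbitrary grouping of the libraries at 0.05. Other splits mix the sexes and put the sex difference into the spread, so they do not measure how many of the calls are false.

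The total per poly(A) site in the deposited table exceeds the sum of the 12 listed libraries by 6.34e+07 counts, against 45443280 in those libraries. As a result, 40428 poly(A) sites in the table have under 25 counts in the 12 libraries, while the start table has 0 counts beyond its libraries. Which libraries the other counts come from is not given in the sources used here, and they enter no comparison.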

How the results depend on the processing

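The gaps between sites, the single strands, the libraries or sites left out because of 1 scaffold, the distances between paired sites, the start sites between them, the thinning of runs, the shares without mitochondrial sites or that scaffold, the mean log2(CPM + 1) difference, the same numbered libraries with no block and the leaving out of single libraries for the assay term and compartment shares were chosen after seeing the data. The other settings were planned. Tests over genes, gene lists and site classes were not run, since the tables name no genes or classes. A changed pseudocount was not run either.

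Without a filter, 30526 poly(A) sites and 35085 start sites differed between the sexes, and 11083 loci in WTTS-seq and 15912 in WTSS-seq. The remaining settings left these counts within 1.5 times of the reported ones. DESeq2 called 9521 poly(A) and 10729 start sites.

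Site use depended most on its settings. For poly(A) sites, 175 runs were called by the Simes form, 1892 with every site of 10 or more counts, 109 with a gap of 500 bases, and 557 with 5000. For start sites these were 1644 with 10 or more counts and 192 and 797 with the gaps. By strand the calls only divided, into 169 of 1069 runs on the plus and 188 of 1422 on the minus strand for poly(A) sites, and 262 of 1018 and 214 of 947 for start sites. Without the 3 libraries with a dominant scaffold, 819 start runs were called, and 473 to 736 with single libraries left out. For the assay term, 333 of 2351 loci were called among those with a mean of 10 CPM or more and 338 of 3779 with a gap of 5000 bases, against 599 of 5401.

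The share of counts on scaffolds in WTTS-seq reversed to -0.368 points when each site was counted once. The distal share difference was 0.434 points with a gap of 500 bases, -0.685 for pairs under 500 bases apart and -0.288 for those with no start between them. The upstream share difference was -1.51 points with a gap of 500 bases and -1.95 without the 3 libraries, both past the threshold, and -1.96 to -0.829 with single libraries left out. The correlation between assays was 0.893 at 10 CPM or more and 0.812 from libraries of separate numbers. For CAGE against WTSS-seq, r was 0.367 at 10 or more counts, 0.360 with the first and 0.396 with the second repeat alone.

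With the replicate number as a replicate block, 7766 poly(A) sites, 11463 start sites (13063 in these libraries unblocked) and 288 and 576 runs (765 unblocked) were called. For the assay term the block was sex and number together, and 167 loci (390 unblocked) were called. With females and males paired by number, the distal share difference was 3.07 points (exact paired permutation p = 0.0313, 6 pairs). The upstream one was -1.77 (exact paired permutation p = 0.25, 3 pairs). Each p is the smallest that many pairs can give. The numbers gave no clear link between libraries. With the sex means removed, same-numbered libraries correlated over 4137 loci at a mean r of 0.000942 between assays in females, 0.0148 in males (at most 0.131, in 1 of 3), and between females and males -0.0704 in WTSS-seq and -0.0181 in WTTS-seq.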

Other observations

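The dependence of the distal share on distance was tested only after that result was seen, and the window on chromosome 9 was singled out after its values were seen. Male-higher loci gathered in few places along the chromosomes. Of 890 windows of 1000000 bases tested by WTTS-seq and 848 by WTSS-seq, 11 and 14 were rich in male-higher loci, 7 of them in both, while 1 and 0 were rich in female-higher loci. These counts rest on p-values that treat neighbouring loci as independent. The test asked for 20 windows in both for a general gathering and 0 for none, so 7 windows leave it open whether sex-biased loci of 1 direction gather in general. Start runs on opposite strands within 1000 bases of each other had correlated sex differences to a small degree (Pearson's r = 0.212 over 318 pairs, against 0.0388 over 973 pairs 20000 to 50000 bases apart). That gap is above the bound set for none and below that set for a shared difference, so its meaning stays open.

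Males had the higher distal poly(A) share, by 3.07 points. A listed start of another transcript between the 2 sites is argued against as the whole cause, since the difference was 3.43 points over pairs with none. Starts with a total under 25 counts are not listed, so this test cannot exclude them. Fewer counts per run in males are too for the 2175 of 8599 runs with 20 or more counts in every library, since over these it was 3.70 points with each run thinned to 20 counts. The other runs were not thinned. The difference grew with the distance between the sites, from -0.685 points under 500 bases to 7.06 at 1000 bases or more. Sites that far apart may end different transcripts, so a sex difference in the choice between ends of 1 transcript stays open. A different tissue makeup of male and female bodies may be behind the difference. Neither that nor sex within a tissue was tested.

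The clusters of sites differed in width between the strands. Poly(A) clusters had a median width of 123 bases on the plus and 26 on the minus strand, and start clusters 78 and 141. Higher counts on the wider strand are argued against, since at matched counts the ratio of widths was 5.79 for poly(A) and 1.82 for start sites. So is the gene content of single chromosomes, since all 20 comparisons (10 chromosomes in each assay) went the same way. Whether 1 end of each aligned read is recorded on both strands stays open. Neighbouring sites under 100 bases apart were more frequent on the narrow strand, by 3.12 times for poly(A) and 2.40 times for start sites, but clusters that wide cover such neighbours whatever made them wide. No biological explanation was tested.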
